A study of Mus musculus with 6 samples.

How the data were processed

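RNA-seq libraries of glomeruli isolated by perfusion with magnetic beads were compared between 3 KO and 3 WT mice. The labels give a directional library kit. Groups and replicate numbers were taken from the sample titles. Titles and genotypes name separate mice per sample, and the design text speaks of 3 mice per group.

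A single deposited table holds, for 27179 features named by NCBI Gene identifiers, normalised counts of each library, a signal that the authors made by dividing reads per gene by a size factor per library, per the file headers and the values themselves. Per the submitters' processing notes, the tools were bcl2fastq 2.19, cutadapt 1.16.5, HISAT2 2.1, featureCounts 1.6.4 and DESeq2 2.11.40.6, the last in the numbering of a workflow wrapper, with the mouse build mm10. The strand setting, the annotation release, the mapping filters and the treatment of reads with several positions are not given in the sources used here. Without the strand setting, reads of overlapping and antisense genes cannot be told apart, and members of multigene families such as Ugt2b, Cyp2c, globins and keratins can share reads.

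Every value was a whole multiple of a step per library, and 100% of the values in each library were whole at a tolerance of 0.01 after division by that step. Whole reads were recovered in this way, 11886828 to 20552984 per library, and size factors computed from them equalled the deposited scaling. The 10 genes far above all other libraries in a single library (at least 30 times, and at least 1000 normalised counts) were listed. Without them the whole reads were 11283413, 11945954 and 13893716 in WT-1, WT-2 and WT-3 and 14310785, 12673591 and 11858362 in KO-1, KO-2 and KO-3. Counting floors cover counting error only, since the reads carry no molecular identifiers. Symbols and mm10 coordinates came from a RefSeq gene table of the same assembly (25275 identifiers) and otherwise from GENCODE M21 (25293 named in all). The 1886 unnamed identifiers, holding 0.493% to 1.29% of the reads of a library, stayed in the tests and are not named.

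The main test was limma 3.58.1 in R 4.3.3 with a trend of the variance, on log2(normalised count + 1), for the 13946 genes with a mean of at least 10 over the 6 libraries, with Benjamini-Hochberg adjustment and a two-sided threshold of 0.05. Fold changes are on this log scale and understate the change of low genes. The design had genotype as its only term. Gene lists (30, fixed before the data were examined) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. They cover the ILK-PINCH-parvin complex, integrin adhesome, slit diaphragm, podocyte, endothelial, mesangial, smooth muscle and renin, parietal, proximal and distal tubule, immune and erythroid markers, basement membrane, fibrotic matrix, YAP and TAZ, SRF and MRTF, immediate early, injury, TGF-beta, NF-kB, interferon, proliferation, p53, unfolded protein response, cholesterol, oxidative phosphorylation, mitochondrial transcripts, ribosomal proteins and junctions. Genes are named by a rule fixed at the same time: Parva, then the 10 largest log2 changes in each direction among genes past the threshold with a mean of at least 50 and no overlap of the groups, leaving out predicted genes, then up to 4 members with the smallest adjusted p in each list with members past the threshold, then Ilk, Lims1, Lims2, Parvb, Rsu1, Nphs1, Synpo, Podxl and Wt1. A few genes that the rule names and 1 of the 30 lists are not reported, for a reason unrelated to their values. Genes that the rule does not name are given only where said to be chosen after their values were seen, or as part of a count.

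Alternatives were a replicate block, pseudocounts of 0.5 and 5, TMM and upper quartile scaling, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, limma without trend and with a robust prior, other filters, a fold threshold and leaving out each library. edgeR called 2841 genes on the recovered reads and DESeq2 3810. Added after seeing the data were the proximal tubule marker mean as a covariate, scaling to equal endothelial and mesangial markers, leaving out the genes counted mostly in a single library, fry as the count of lists, and edgeR without each library. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 14 within a genotype). The steps were tested on counts simulated from the real means, sizes and dispersions for 13926 genes. Each gene was drawn independently, without the genes counted mostly in a single library, so variation shared by many genes is absent from these counts. In KO against WT, limma recovered 64% of 100 genes changed 2-fold and 95% of 100 changed 4-fold, with 15 false calls. edgeR recovered 64% and 95% with 13 false calls, and DESeq2 74% and 98% with 45.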

Results

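RNA of kidney glomeruli, the filtering units in which podocytes, endothelial cells and mesangial cells lie together, was sequenced from 6 male mice aged 9 weeks on a mixed C57BL/6 background. The labels describe the mice as mildly proteinuric. In 3 mice (KO-1 to KO-3) both copies of Parva were floxed and Cre was active in podocytes. The other 3 mice (WT-1 to WT-3) carried the floxed gene without Cre. Parva encodes alpha-parvin, an actin-binding partner of integrin-linked kinase at cell-matrix adhesions. The comparison asks which glomerular transcripts differ when the gene is deleted in podocytes. The whole-read totals recovered from the normalised counts were 16147655, 14456490 and 20552984 in WT-1, WT-2 and WT-3. They were 20015813, 12704198 and 11886828 in KO-1, KO-2 and KO-3. Part of this depth lay in 10 genes that were each at least 30 times higher in 1 library than in any other. These genes, which include Pxn and Vegfa in KO-1, took 30.1% of the reads of WT-1, 17.4% of WT-2, 32.4% of WT-3 and 28.5% of KO-1, against 0.241% in KO-2 and 0.239% in KO-3. Pxn stood at 2871730 normalised counts in KO-1 and at most at 1685 elsewhere. Vegfa stood at 781207 in KO-1 and at most at 21599 elsewhere. None of the 10 passed the test between genotypes, which a single outlying library makes hard to pass. Outside KO-1, Vegfa stood at 16662, 19493 and 21599 in WT-1, WT-2 and WT-3 and at 11395 and 10140 in KO-2 and KO-3.

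Parva was lower in every KO library than in any WT library. The gene (NCBI Gene 57342; mm10 chromosome 7, 112427706 to 112591688) had normalised counts of 6585, 7520 and 7890 in the WT libraries and of 2288, 2338 and 1942 in the KO libraries. Its mean fell from 7332 ± 672 (SD, n = 3) to 2189 ± 215 (SD, n = 3), a log2 fold change of -1.74 (SE 0.12, limma adjusted p = 0.0106). A two-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. About 0.299 of the WT level was left in libraries of whole glomeruli, which also hold cells without Cre. A count per gene does not show whether the reads lie inside or outside the floxed part. The adjusted p rose above the threshold without WT-2 (0.0793) and without WT-3 (0.0533), at log2 fold changes of -1.72 and -1.69, and was 0.581 at a log2 fold change of -1.48 with the proximal tubule marker mean as a covariate, an alternative chosen after seeing the data.

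**Figure D1:**
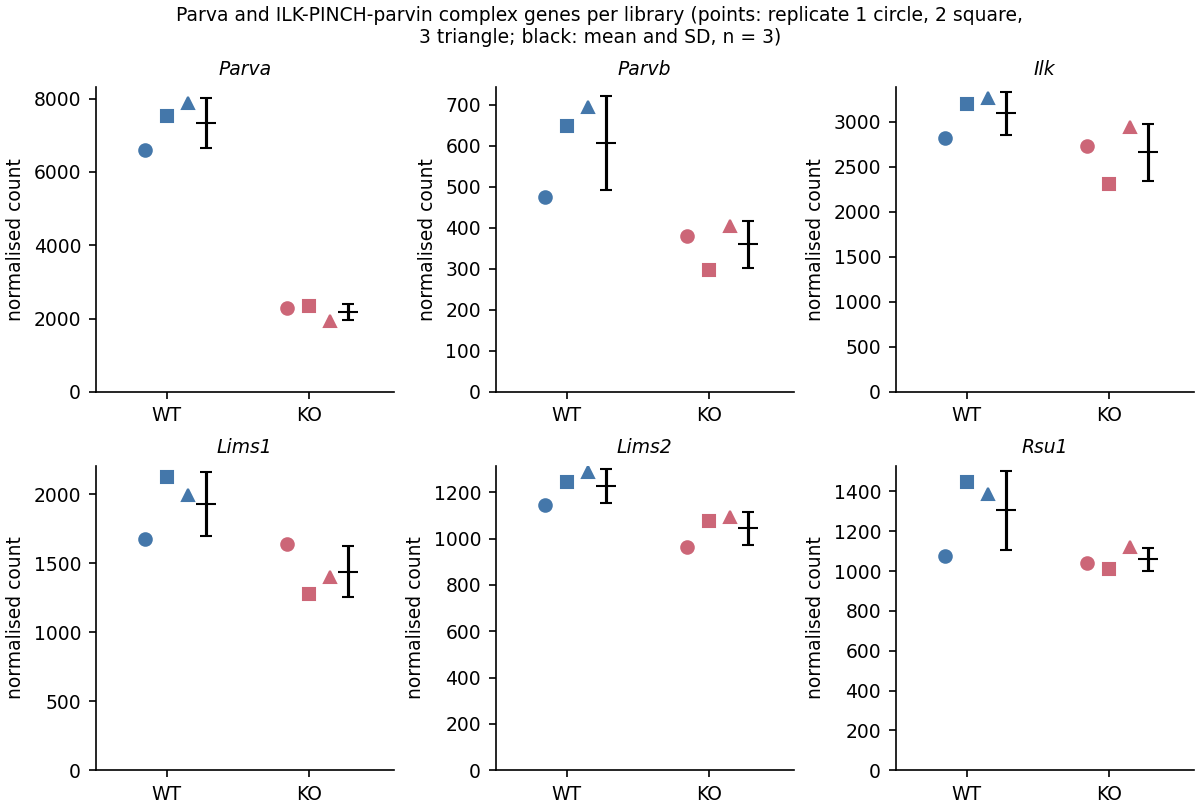
Normalised counts of Parva and of 5 genes of the ILK-PINCH-parvin complex in the 3 WT and 3 KO libraries, on linear axes from 0; points are libraries and black bars are the mean and SD. Parva lay between 6585 and 7890 in WT and between 1942 and 2338 in KO; Parvb also passed the test, whereas Ilk, Lims1, Lims2 and Rsu1 did not.

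Beyond Parva, transcripts of tubule and mitochondrial metabolism were higher and those of endothelial, mesangial and several podocyte genes lower in the KO libraries. Of the 13946 genes tested, 3085 passed an adjusted p of 0.05 in limma, 1889 of them higher and 1196 lower in KO. A difference of at least 2-fold was present in 1084 of them, 964 higher and 120 lower. In 6293 genes, or 45.1%, the KO and WT libraries did not overlap, where chance gives 10% for a single gene. Genes moved together, as the first principal component, a single axis of variation, held 61.4% of the variance between libraries. The share therefore cannot be weighed as if the genes were independent. Scaling the libraries to their upper quartile changed the split to 1717 higher and 1530 lower. Scaling them to equal endothelial and mesangial marker levels, an alternative chosen after seeing the data, added 0.60 to the median log2 change of all genes, and 8764 of 8826 calls were then higher in KO. All directions below are relative to the median of the genes tested, which was -0.006 on the log2 scale with the deposited scaling. The count was 1 in limma without the variance trend, with 5305 genes at an unadjusted p below 0.05, and 0 in limma with the proximal tubule marker mean as a covariate (450 at an unadjusted p below 0.05), against 2841 in edgeR and 3810 in DESeq2 without that covariate. Nor was it stable to the loss of a library: limma called 1 gene without WT-2, 0 without WT-3, 4 without KO-2 and 3 without KO-3, with 3939, 4048, 4021 and 4924 genes at an unadjusted p below 0.05. edgeR called 1, 0, 0 and 1 gene in these fits. Leaving out WT-1 gave 4294 calls and leaving out KO-1 gave 2062 (1186 in edgeR).

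**Figure D2:**
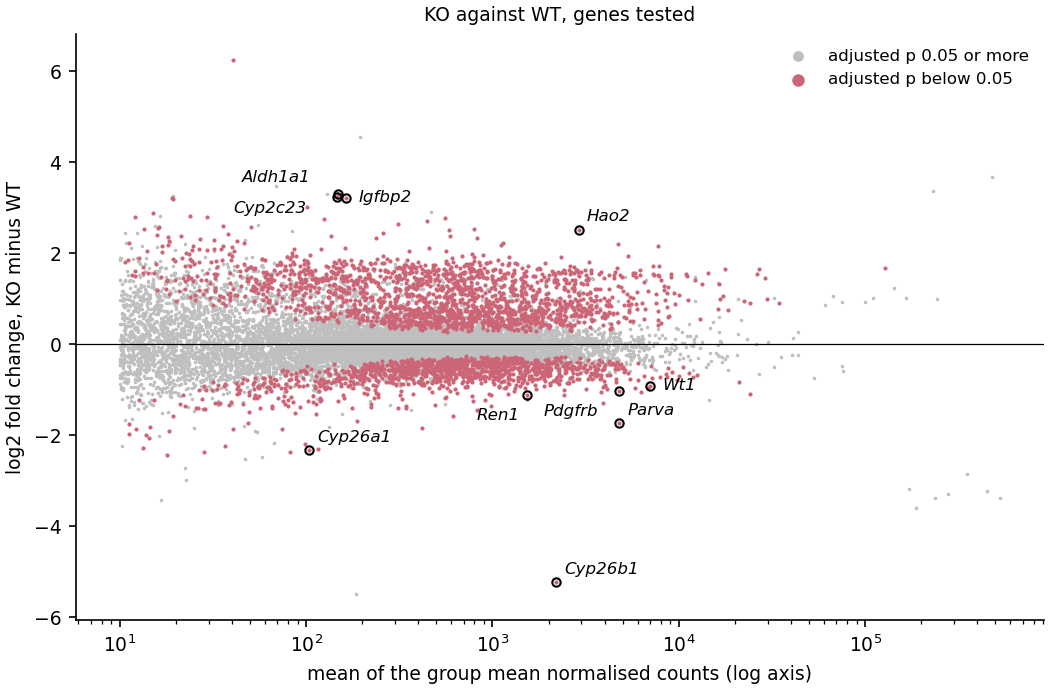
Log2 fold change (KO minus WT) of each gene tested against the mean of its group mean normalised counts, on a log axis; red points passed an adjusted p of 0.05 in limma. Of the 13946 genes, 1889 were called higher and 1196 lower in KO; Cyp26b1 lay at -5.23 and Parva at -1.74, and the grey points on the far right include the genes counted mostly in 1 library.

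Among the genes with a mean of at least 50 and no overlap between the groups, Cyp26b1 had the largest decrease. This enzyme, which degrades retinoic acid, had normalised counts of 2101, 4085 and 6147 in WT and of 630, 9 and 163 in KO (log2 fold change -5.23, SE 1.36, limma adjusted p = 0.0371). Its relative Cyp26a1 fell from 174 ± 58.7 to 33.3 ± 10.3 (SD, n = 3), a log2 fold change of -2.33 (SE 0.34, limma adjusted p = 0.0286). The other 8 of the 10 largest decreases were Slc7a2 (a cationic amino acid transporter), Cnmd, Gja3, Adra2c (an adrenergic receptor), Ptpru, Parva, Scn7a and Astn2, with log2 fold changes from -2.37 to -1.59. The 10 largest increases were Aldh1a1, Cyp2c23, Igfbp2, Fgg, Ugt2b37, Gc, Cpn1, Bhmt, Sult1c2 and Hao2, from 3.29 for Aldh1a1, a retinaldehyde dehydrogenase, to 2.52 for Hao2, a peroxisomal hydroxyacid oxidase. Aldh1a1 rose from 25.1 ± 10.5 to 270 ± 168 (SD, n = 3), with 464 in KO-3 and 181 and 166 in KO-1 and KO-2. Cyp2c23, a cytochrome P450 of arachidonate metabolism, rose from 29.6 ± 14.3 to 264 ± 55.9 (SD, n = 3). Fgg, a fibrinogen chain, was uneven among the KO libraries, at 45, 128 and 383. Ugt2b37 was at 476 in WT-1 and at 93 and 46 in WT-2 and WT-3, and its log2 fold change was -0.51 with the proximal tubule marker mean as a covariate. Hao2 (1904, 348 and 838), Sult1c2 (404, 170 and 157) and Gc (62, 22 and 16 in WT-1, WT-2 and WT-3) were also highest in WT-1 among the WT libraries. So were Aldh1a1, Fgg and Bhmt, and so were the proximal tubule markers described below. Cyp2c23, Igfbp2 and Cpn1 were highest in WT-2.

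Markers of kidney tubules were higher in KO and markers of glomerular endothelial and mesangial cells were lower. Of 24 proximal tubule markers, 22 rose and 2 did not pass (23 rose when adjusted over the list alone), with a median log2 fold change of 1.52. Miox rose from 3764 ± 1691 to 11840 ± 2330, Gatm from 3699 ± 1417 to 9251 ± 1637 and Cubn, a receptor for filtered protein, from 763 ± 338 to 2173 ± 561 (SD, n = 3). The mean log2 level of the list was 12.55 in WT-1, 11.4 in WT-2 and 11.36 in WT-3, against 12.88, 13.46 and 13.34 in KO-1, KO-2 and KO-3, so that WT-1 lay closer to KO-1 than to the other WT libraries. Of 20 distal tubule and collecting duct markers, 3 rose, namely Aqp3, Fxyd4 and Scnn1b (13 adjusted over the list alone), and all 20 had a higher KO mean, but Aqp3 and Fxyd4 were at -0.10 and -0.16 with the proximal tubule marker mean as a covariate. The count of 3 was 0 in edgeR, 11 in DESeq2, 0 in limma without KO-1 and 17 in limma without WT-1. Of 25 glomerular endothelial markers, 19 fell and 6 did not pass (22 fell adjusted over the list alone), with a median of -0.60. They include the VEGF receptor Flt1, from 2448 ± 207 to 1505 ± 77.5, and Sox17, from 1166 ± 131 to 668 ± 94.7 (SD, n = 3). Of 18 mesangial markers, 11 fell (12 adjusted over the list alone), with a median of -0.63, among them Pdgfrb from 6410 ± 1323 to 3114 ± 210 and Tbx3 from 2623 ± 399 to 1441 ± 55.5 (SD, n = 3). All 4 lists passed limma's camera test with a preset correlation of 0.01, with adjusted p = 5.57e-10, 3.57e-05, 3.31e-11 and 1.21e-07 in the order given. None passed with an estimated correlation (adjusted p = 0.605 for each). With the proximal tubule marker mean as a covariate, the endothelial and mesangial lists passed camera at the preset correlation (adjusted p = 2.64e-09 and 3.79e-05), at medians of -0.32 and -0.25. The distal list did not (adjusted p = 0.783). No list was tested with an estimated correlation or by fry with this covariate. Fitted as list means per library with the covariate, endothelial markers changed by -0.32 (SE 0.15) and mesangial markers by -0.28 (SE 0.13). The preset correlation treats the genes of a list as nearly independent, so these camera values do not settle whether the lower levels outlast the adjustment.

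**Figure D3:**
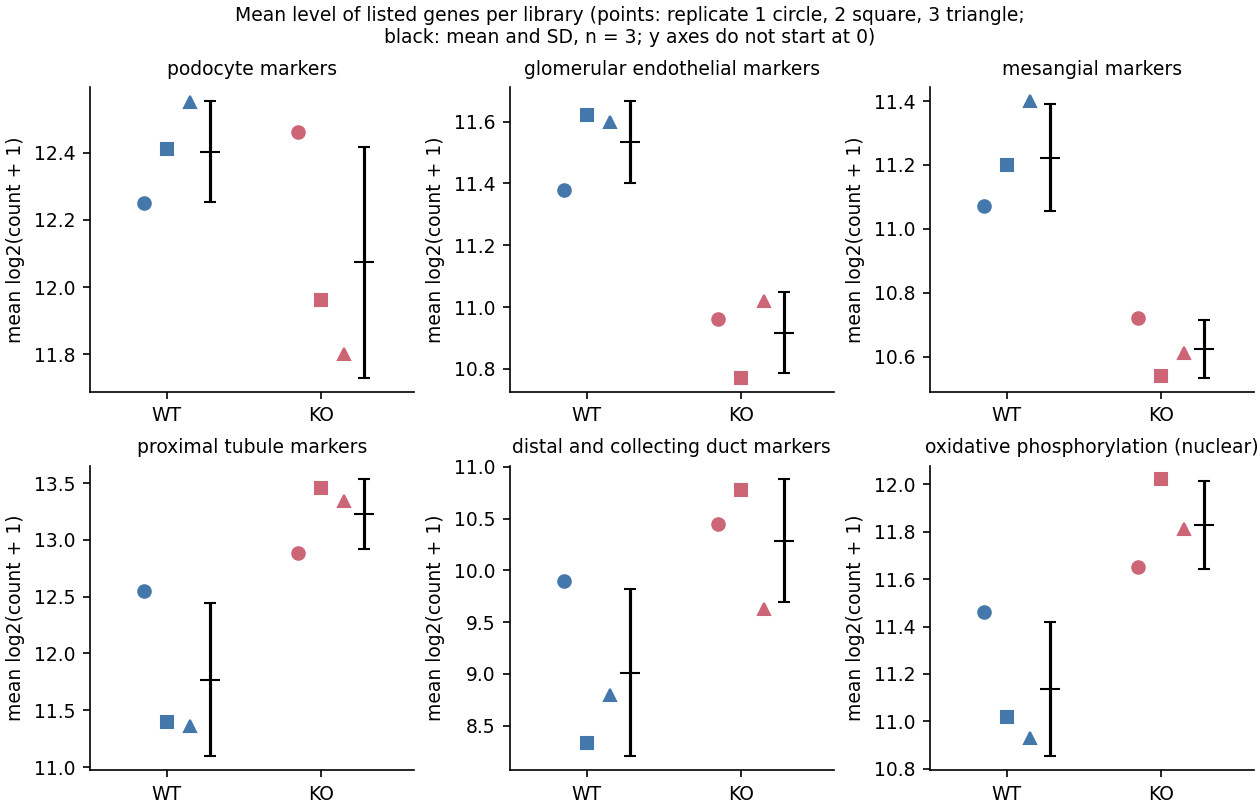
Mean log2(normalised count + 1) of the genes of 6 lists in each library, with black bars for the mean and SD of 3 libraries per genotype; the axes do not start at 0. Proximal tubule markers lay between 11.36 and 12.55 in WT and between 12.88 and 13.46 in KO, and endothelial markers between 11.38 and 11.62 in WT and between 10.77 and 11.02 in KO.

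Renin and its companion enzyme were lower. Ren1 fell from 2084 ± 151 to 972 ± 189 and Akr1b7 from 333 ± 16.5 to 152 ± 48.1 (SD, n = 3), and Myh11, a smooth muscle myosin, fell from 328 ± 34.8 to 204 ± 4.34 (SD, n = 3). Tagln, another contractile gene, rose from 610 ± 52.1 to 2000 ± 1202 (SD, n = 3), with 3386 in KO-3 and 1254 and 1359 in KO-1 and KO-2. The list of 9 measured smooth muscle and renin cell genes did not pass (camera adjusted p = 0.114). Among 15 markers of the parietal epithelium that lines Bowman's capsule, 6 rose and 2 fell (9 and 2 adjusted over the list alone). Cldn1 rose from 236 ± 47.4 to 507 ± 98.5, Pax8 from 246 ± 76.5 to 506 ± 35.8 and the keratin Krt18 from 46.7 ± 25.5 to 148 ± 24.4, whereas Cd24a fell from 7753 ± 916 to 3949 ± 409 (SD, n = 3). Krt8, Krt18 and Pax8 are also expressed in tubules, whose markers rose in the same libraries. This list passed camera (adjusted p = 0.022), not with an estimated correlation (adjusted p = 0.605), and not without KO-1 (adjusted p = 0.053). With the proximal tubule marker mean as a covariate it did not pass either (adjusted p = 0.605), and its median went from 1.10 to 0.12. Of 21 measured immune cell markers none passed (camera adjusted p = 0.128, but 0.0168 without WT-3 and 0.000848 without KO-2, against 0.929 without KO-3, where the median went from 0.38 to -0.01, and 0.000267 with the proximal tubule marker mean as a covariate, at a median of 0.84), and the list mean was 7.7 in KO-3 against 5.62 to 6.47 in the other libraries. Of 4 measured erythroid transcripts, Hbb-b1 and Hbb-bs fell (Hbb-bs was at 0.05 with the proximal tubule marker mean as a covariate), and the list did not pass (camera adjusted p = 0.118, but 0.0373 without WT-1). It also passed camera with a minimum mean of 1 (adjusted p = 0.0418), with no filter (0.0308) and with endothelial and mesangial markers set equal (7.51e-05). Near-identical globin copies can share reads, so the change of each is uncertain.

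Nuclear genes of oxidative phosphorylation rose together. Of 52 genes, 45 rose, 7 did not pass and all 52 had a higher KO mean, with a median log2 fold change of 0.70 (camera adjusted p = 8.62e-16). Examples are Uqcrc1 of complex III, from 3129 ± 630 to 5528 ± 662, Cox8a of complex IV, from 3209 ± 355 to 5262 ± 652, and Sdhd of complex II, from 1991 ± 363 to 3412 ± 452 (SD, n = 3). Of 15 transcripts of the mitochondrial genome, 7 rose (10 adjusted over the list alone), among them ATP6 from 772 ± 132 to 1810 ± 511 and ND3 from 91.4 ± 15.4 to 211 ± 32.6 (SD, n = 3; camera adjusted p = 1.19e-05). Neither list passed with an estimated correlation (adjusted p = 0.605). Both moved with the proximal tubule markers, whose mean as a covariate left a median of 0.05 in the nuclear list (adjusted p = 0.147) and an adjusted p of 0.0911 in the mitochondrial list. In cholesterol synthesis, 6 of 21 genes rose and none fell (7 adjusted over the list alone). Mvd, of the mevalonate pathway, rose from 185 ± 46.6 to 416 ± 87.8 (SD, n = 3). This list passed camera (adjusted p = 0.00263, median 0.37), also with the proximal tubule marker mean as a covariate (adjusted p = 0.00322), where the median was 0.20, and it was the list that passed fry, a self-contained test of a common direction (adjusted p = 0.0456), but it did not pass with an estimated correlation (adjusted p = 0.605).

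Among the other 6 genes of the ILK-PINCH-parvin complex, only the paralogue Parvb passed the test. Parvb fell from 606 ± 115 to 360 ± 56.7 (SD, n = 3), a log2 fold change of -0.75 (SE 0.18, limma adjusted p = 0.0325). The log2 fold changes of the others were -0.22 for Ilk (limma adjusted p = 0.202), -0.43 for Lims1 (0.0554), -0.23 for Lims2 (0.107), -0.29 for Rsu1 (0.131) and 0.01 for Parvg (0.989), the last chosen after its value was seen. The 7 genes of the complex, Parva included, passed camera (adjusted p = 0.00446), not with an estimated correlation (adjusted p = 0.605). Parva, the deleted gene, contributes to this call, and the other 6 genes were not tested as a list of their own. In the wider list of 55 integrin adhesome genes, 11 fell, Parva and Parvb among them, and 3 rose (13 and 3 adjusted over the list alone). Fhl2, a LIM-domain protein, fell from 2909 ± 391 to 1691 ± 193, whereas the talin gene Tln2 rose from 428 ± 188 to 1256 ± 206 and Src from 232 ± 29 to 356 ± 17.2 (SD, n = 3). Tln2 was uneven in WT, at 642 in WT-1 and at 356 and 286 in WT-2 and WT-3, highest in WT-1 as were the proximal tubule markers. The list passed as lower (camera adjusted p = 0.00446), not with an estimated correlation (adjusted p = 0.605), and its median of -0.20 was below its mean of -0.09, which includes the value of Pxn in KO-1. With the proximal tubule marker mean as a covariate, the complex and the adhesome list did not pass (adjusted p = 0.293 and 0.93).

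Of 34 podocyte markers, 10 fell, 2 rose and 22 did not pass (14 fell and 2 rose adjusted over the list alone). Wt1, a transcription factor of podocytes, fell from 9176 ± 1639 to 4827 ± 820, Foxc2 from 1850 ± 135 to 1031 ± 142, Thsd7a from 5140 ± 1169 to 2482 ± 475 and Plce1 from 2786 ± 256 to 1766 ± 246 (SD, n = 3). Nephrin (Nphs1) had means of 19510 ± 1925 in WT and 15810 ± 3285 in KO (SD, n = 3; limma adjusted p = 0.265). Synpo and Podxl had log2 fold changes of -0.66 and -0.59 (limma adjusted p = 0.0583 and 0.178). Of 15 slit diaphragm genes, 6 fell (8 adjusted over the list alone), among them the scaffold Magi2 from 2081 ± 276 to 1365 ± 144 and the kinase Fyn from 2031 ± 222 to 1357 ± 186 (SD, n = 3). Both lists passed camera as lower (adjusted p = 0.000533 for markers and 0.000222 for the slit diaphragm), not with an estimated correlation (adjusted p = 0.62 and 0.605). The marker list had a median of -0.48 and a mean of -0.33, and its mean level in KO-1, 12.46 with Vegfa included, lay within the WT range of 12.25 to 12.55. Without Vegfa the level in KO-1 was 12.24, again within the WT range, then 12.2 to 12.49. With the proximal tubule marker mean as a covariate, the markers had a median of 0.07 (adjusted p = 0.783) and the slit diaphragm list did not pass (adjusted p = 0.853).

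Several signalling and matrix lists were lower or mixed. Of 26 measured interferon response genes, 6 fell and none rose (8 adjusted over the list alone), with Gbp7 from 780 ± 67.9 to 473 ± 95.3 and Usp18 from 159 ± 13.4 to 103 ± 13.9 (SD, n = 3; camera adjusted p = 3.75e-05). Of 28 measured genes of fibrotic matrix, 4 fell and none rose (2 adjusted over the list alone). Postn fell from 128 ± 17.5 to 47.2 ± 23.2, Col6a3 from 418 ± 82.7 to 228 ± 37, Bgn from 4962 ± 569 to 3642 ± 147 and Tgfbi from 208 ± 27.1 to 133 ± 27.2 (SD, n = 3; camera adjusted p = 0.0205, and 0.228 without KO-2). Of 20 TGF-beta response genes, 6 fell and 2 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.0205, and 0.0807 without KO-1). The count of lower genes was 1 without KO-1 and 9 without WT-1. The pseudoreceptor Bambi, a TGF-beta antagonist, fell from 785 ± 130 to 437 ± 52.1, and Id2 rose from 1245 ± 361 to 2406 ± 534 (SD, n = 3). Of 27 proliferation genes none passed singly, and 22 had a higher KO mean (camera adjusted p = 0.0476). This last call ended without WT-1 (adjusted p = 0.281), WT-2 (0.0912), KO-1 (0.0776) or KO-3 (0.401), with a minimum mean of 50 (0.539) and with endothelial and mesangial markers set equal (0.713). None of these 4 lists passed with an estimated correlation (adjusted p = 0.605, 0.62, 0.605 and 0.682). With the proximal tubule marker mean as a covariate, the first 3 did not pass (adjusted p = 0.0925, 0.79 and 0.0925) and proliferation did (4.36e-05).

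**Figure D4:**
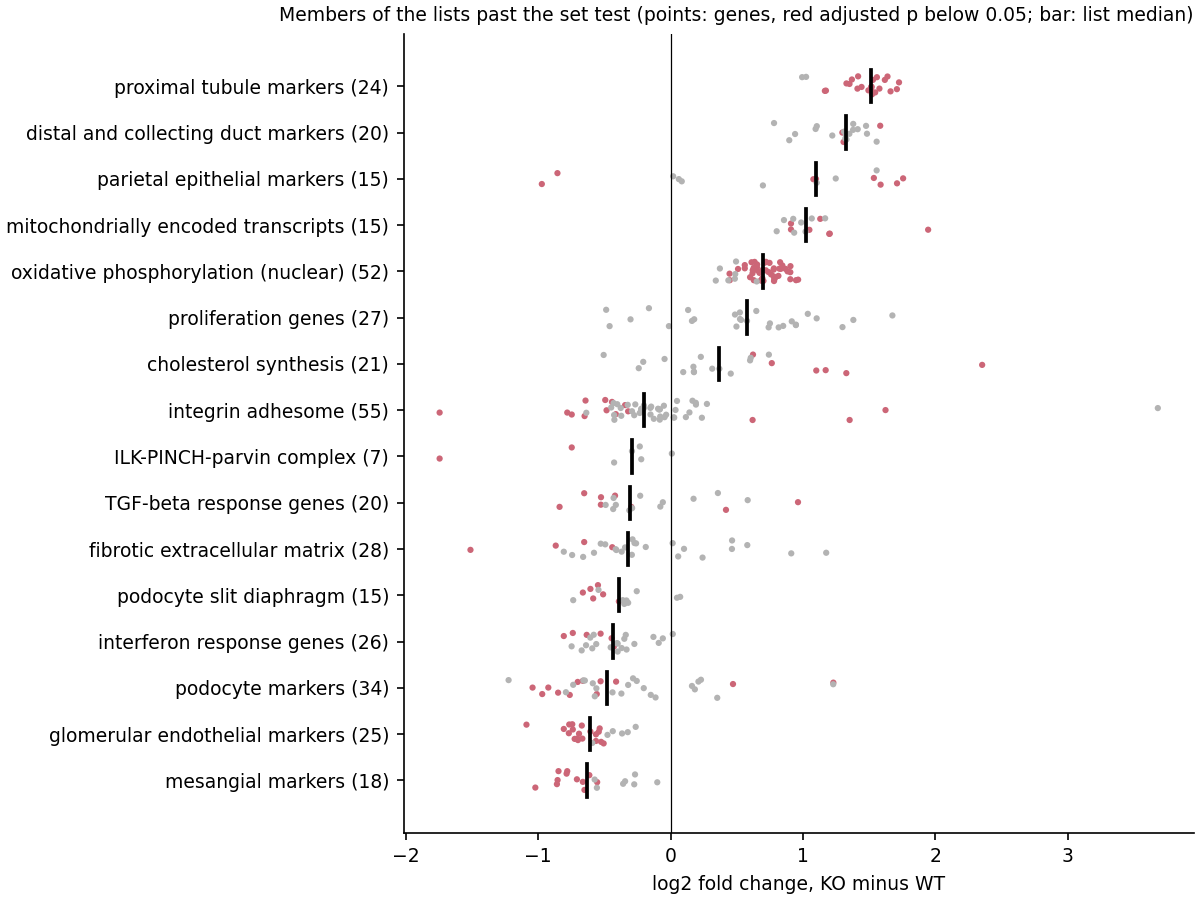
Log2 fold change (KO minus WT) of each measured member of 16 of the 17 lists that passed camera, with red points for genes past an adjusted p of 0.05 in limma and a black bar for the list median; numbers in brackets are genes measured. Medians ran from -0.63 for mesangial markers to 1.52 for proximal tubule markers; the point at 3.68 in the adhesome list is Pxn.

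The other lists did not pass camera. Among 21 measured YAP and TAZ target genes, 4 rose and 4 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.147). Ccn1, a matricellular protein, rose from 718 ± 63.2 to 1507 ± 103 and Crim1 from 3999 ± 257 to 6128 ± 910, whereas Amotl1 fell from 3697 ± 428 to 2151 ± 120 and Dlc1 from 5304 ± 520 to 3287 ± 279 (SD, n = 3). Of 21 measured SRF and MRTF targets, 3 rose and 2 fell (camera adjusted p = 0.398). Of 21 measured immediate early genes, 2 rose, Ier3 and Maff, and 3 fell, with Klf2 from 2952 ± 419 to 1598 ± 104 and Klf4 from 1586 ± 127 to 872 ± 147 (SD, n = 3; camera adjusted p = 0.255, but 6.74e-06 with the proximal tubule marker mean as a covariate, where the median went from -0.15 to -0.48). Among 27 measured genes of the glomerular basement membrane, 3 rose and 4 fell (camera adjusted p = 0.569). The laminin chain Lama1 rose from 38.5 ± 14.5 to 117 ± 9.1 and Frem1 from 32.4 ± 4.95 to 132 ± 60, whereas Tinagl1 fell from 4132 ± 626 to 2411 ± 344 and Col15a1 from 1310 ± 185 to 840 ± 91.1 (SD, n = 3). Among 24 measured genes of junctions and polarity, 4 rose and 2 fell (camera adjusted p = 0.343), with Mpp5 from 5233 ± 575 to 2837 ± 522 and Prkcz from 331 ± 122 to 738 ± 83.8 (SD, n = 3). In this list and in the basement membrane list the median (-0.10 and -0.06) and the mean (0.13 and 0.05) differed in sign. Of 28 measured kidney injury genes, 5 rose and 1 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.0825, but 0.0301 without WT-2, 0.0422 without KO-1 and 0.00291 without KO-2, against 0.191 without WT-1 and 0.414 without KO-3, where the median went from 0.94 to 0.43, and 0.0192 with the proximal tubule marker mean as a covariate, at a median of 0.45). Clu rose from 1807 ± 632 to 4322 ± 683 and Hbegf fell from 674 ± 69.4 to 460 ± 31.7 (SD, n = 3). The mean of the injury list was 9.69 in KO-3, 8.41 and 8.32 in KO-1 and KO-2, and 7.82 to 7.93 in WT. Of 21 measured NF-kB and chemokine genes, Cxcl12 rose and Csf1 fell (camera adjusted p = 0.398, 0.929 without KO-3, but 0.0261 without KO-2 and 0.00502 with the proximal tubule marker mean as a covariate, where the median went from 0.18 to 0.38). Of 20 p53 targets, Sesn2, Ccng1 and Perp rose (camera adjusted p = 0.346), but Perp was at -0.30 with the proximal tubule marker mean as a covariate. Adjusted over the list alone, 4 p53 targets rose and 3 fell. Of 50 cytosolic ribosomal protein genes, Rps2 and Rpsa rose (camera adjusted p = 0.255, but 0.0191 without WT-2), and 0 passed when adjusted over the list alone. Of 24 measured genes of the unfolded protein response none passed (camera adjusted p = 0.769, but 0.00662 without KO-3; median 0.03, mean -0.02).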

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

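Of these tests, those with the tubule marker covariate, with glomerular marker scaling, without the single-library genes, by fry and by edgeR without a library were chosen after seeing the data. The count of 3085 genes stayed within 1.5 times under both pseudocounts, TMM and upper quartile scaling, edgeR (2841), DESeq2 (3810), a robust prior, the other filters and without the single-library genes, from 2668 to 3810 calls, of which 2600 to 3084 were shared with it. It was 1 without the trend (5305 genes at an unadjusted p below 0.05), 1084 with a log2 fold change of at least 1, and 8826 with glomerular marker scaling, which adds 0.60 to the median change. With the tubule marker covariate limma called 0 genes (450 at an unadjusted p below 0.05; edgeR was not run with it); this covariate shares 0.74 of its variance with genotype and costs a degree of freedom. Leaving out a library gave 0 to 4294 calls in limma and 0 to 4307 in edgeR. In edgeR the counts were 1 without WT-2, 0 without WT-3, 1186 without KO-1, 0 without KO-2 and 1 without KO-3; limma gave 1, 0, 2062, 4 and 3, with 3939, 4048, 5200, 4021 and 4924 genes at an unadjusted p below 0.05. A fit without a library has 1 residual degree of freedom fewer, and the cause of the differences between libraries was not tested.

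The replicate numbers gave no sign of pairing. Same-numbered libraries correlated at -0.226, -0.191 and -0.013 in their deviations from the group means, and none correlated best with its own number. With 3 libraries per group, this cannot exclude a batch shared by libraries of the same number. With a replicate block limma called 0 genes (4284 at an unadjusted p below 0.05; edgeR called 2841 without the block), Parva was at -1.74 (adjusted p = 0.0868) and 19 lists passed.

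Parva stayed lower under all settings, from -1.82 to -1.14, with limma, edgeR or DESeq2 adjusted p from 1.53e-33 to 0.581. It missed the threshold at -1.74 without the trend (0.0537), at -1.48 with the tubule marker covariate (0.581), and without WT-2 or WT-3 in limma. In edgeR it missed it at -1.73 without WT-2 (0.111), -1.69 without WT-3 (0.0944), -1.79 without KO-2 (0.0532) and -1.66 without KO-3 (0.0587). Without a library its log2 fold change lay between -1.82 and -1.66. The number of lists past camera, 17, was 15 to 19 in the other limma fits, but 8 with the tubule marker covariate (cholesterol synthesis, proliferation, kidney injury, NF-kB and immune lists higher; endothelial, mesangial and immediate early lists lower), 0 with an estimated correlation and 1 with fry. Without a library it was 15 to 19.

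Among the genes past the threshold with or without the setting, the sign turned with the tubule marker covariate for Ugt2b37 (-0.51), Myh14 (-0.03), Aqp3 (-0.10), Fxyd4 (-0.16), Hbb-bs (0.05) and Perp (-0.30). The direction camera gives turned for the distal and collecting duct list (median -0.05) and the podocyte list (0.07), and the medians of the proximal (-0.05), complex (0.02), slit diaphragm (0.03) and adhesome lists (0.02) crossed 0 too. With glomerular marker scaling, before its shift of 0.60 is taken off, it turned for Rhob (0.03), Ppp1r12a (0.08), Bgn (0.17), Ifit2 (0.08), Irf9 (0.16), Hbegf (0.06), Csf1 (0 when rounded), Magi2 (0 when rounded), Fyn (0.02), Nck1 (0.10), Id3 (0.08), Lims2 (0.38), Rsu1 (0.32) and Ilk (0.39); genes past it in neither fit, such as Lims1 and Nphs1, turned too. So did the medians of 9 of the 17 lists, and the TGF-beta (adjusted p = 0.0913), distal (0.171), adhesome (0.346), parietal (0.618) and proliferation lists (0.713) no longer passed. The erythroid (camera adjusted p = 7.51e-05), ribosomal (0.00621), immediate early (0.026) and smooth muscle and renin lists (0.0458), which had not passed before, passed in that fit. Depth without the single-library genes was 11283413 to 13893716 reads per library in WT and 11858362 to 14310785 in KO, and in simulated libraries of this size limma recovered 64% of 2-fold changes, so changes of that size can be missed.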

Other observations

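The genes and tests in this part were chosen after seeing the data, except the count over splits of the libraries. Some genes that handle retinoids passed the test and others did not; they come from no fixed list and were not tested as a group. Beside Cyp26b1 and Cyp26a1, which degrade retinoic acid and were lower in KO, the retinoic acid receptor Rarb fell from 428.9 ± 49.9 to 216.1 ± 75.7 (SD, n = 3), a log2 fold change of -1.03 (limma adjusted p = 0.0304). Aldh1a1, a retinaldehyde dehydrogenase, was higher, Rdh10, a retinol dehydrogenase, rose from 406.5 ± 110 to 714.8 ± 77.3 (limma adjusted p = 0.0304), and Ttr, a carrier in the retinol transport complex of plasma, rose from 186 ± 34.8 to 992 ± 292 (SD, n = 3; limma adjusted p = 0.0262). Rdh10 was at 533.4 in WT-1 and at 334.5 and 351.4 in WT-2 and WT-3, highest in WT-1 as were the proximal tubule markers. Stra6, a receptor for retinol transport, rose from 3.29 ± 1.87 to 29.1 ± 25.9 (SD, n = 3; limma adjusted p = 0.0361). Its reads were few and uneven, at 5, 2 and 3 in WT-1, WT-2 and WT-3 and 15, 14 and 52 in KO-1, KO-2 and KO-3. Aldh1a2 and Aldh1a3 had log2 fold changes of 0.09 and -0.39 that did not pass (limma adjusted p = 0.802 and 0.256), and Cyp26c1 was too low to be tested. Cyp26a1 and Aldh1a1 lie on chromosome 19, which also holds the cluster of raised genes described below. The number of genes called depends on single libraries: limma called 1 without WT-2, 0 without WT-3, 4 without KO-2 and 3 without KO-3, with 3939, 4048, 4021 and 4924 at an unadjusted p below 0.05 (edgeR called 1, 0, 0 and 1).

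Further single genes, from no fixed list and not tested as a group, also passed. Plau (urokinase) rose from 2079 ± 163 to 3790 ± 438, Dock8, a guanine nucleotide exchange factor, from 1351 ± 83 to 4137 ± 1454 and Pamr1 from 172 ± 23.4 to 1001 ± 256, whereas Pdgfra fell from 1343 ± 150 to 617 ± 53.1 and Pi16 from 5475 ± 434 to 2773 ± 131 (SD, n = 3; limma adjusted p = 0.0286, 0.0286, 0.0106, 0.0262 and 0.0262). KO-3 stood apart in several genes. Havcr1 was at 678.1 normalised counts there, 27.5 and 43.3 in KO-1 and KO-2 and 7.6 to 10.7 in WT, and Lcn2 was at 357.2, against 19.5 and 23.8 in KO-1 and KO-2 and 2.5 to 8.7 in WT. Ccl2 was at 100.9 in KO-3 against 5.3 and 6.5 in KO-1 and KO-2, C3 at 1415.2 against 223.3 and 113.7, Mmp10 at 96.4 against 2.7 and 0, Col5a3 at 213.2 against 21.3 and 13 and Gdpd2 at 280.1 against 12.4 and 8.7. None of these 7 passed (limma adjusted p = 0.0663, 0.0574, 0.0736, 0.193, 0.222, 0.326 and 0.671). The mean of the NF-kB and chemokine list was 8.66 in KO-3 and 7.49 to 7.85 in the other libraries.

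Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one with 3085 genes, gave as many calls, and the highest of the others gave 1; 10 splits are too few for a share under 0.05.

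Tubule markers were higher and many markers of glomerular cells lower in KO, and a larger share of tubule RNA in the KO libraries, which the isolation with beads would reduce, is a candidate explanation; its first tests, the differences of endothelial minus mesangial (-0.01, SE 0.08), proximal minus distal (0.17, SE 0.42) and podocyte minus endothelial markers (0.24, SE 0.17), all lay within 2 SE of 0 and were replaced by the tests below after a trial fit had shown their outcome. All 24 proximal markers were also measured in WT, and the most abundant, Kap, had means of 74770 ± 36830 in WT and 145600 ± 44330 in KO (SD, n = 3; limma adjusted p = 0.143). The share as the whole cause of the drop of Parva is argued against by its fall of 0.66 (log2 change of Parva minus Plat -0.66, SE 0.15) beyond that of Plat, the endothelial marker that fell furthest. With the proximal marker mean in the model, the change of the oxidative phosphorylation mean went from 0.69 to 0.05 (SE 0.11), as such a share would give, whereas that of podocyte markers without Vegfa, -0.38 before and 0.03 (SE 0.26) after, has an error too wide to separate no change from the full one, and endothelial and mesangial markers went from -0.61 to -0.30 (SE 0.11) on the log2 scale and from -0.35 to -0.15 (SE 0.08) relative to WT on the linear scale, where the scale decides, so that for these 3 lists a tubule share and a loss of transcripts cannot be told apart. An effect of the genotype on how much tubule comes along cannot be told apart from uneven isolation either, because genotype and tubule markers go together and the gap of 0.32 between the lowest KO and the highest WT library is smaller than the WT range of 1.19.

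Genes raised in KO lay close together on chromosome 19, a region noticed among the genes with the largest changes and then examined with several scan statistics and 3 window sizes. In windows of 20 neighbouring tested genes, the highest mean limma t, 3.03, was at mm10 chromosome 19, 42090148 to 44070164 (permutation p = 0.0043 over 10000 shuffles of gene positions), where 8 of 20 genes rose and 0 fell in limma, among them Abcc2 (from 288 ± 64.5 to 1091 ± 68.3; SD, n = 3), Cpn1, Cyp2c23, Erlin1 and Cox15; windows of 10 genes peaked there too (p = 0.001, the smallest that 1000 shuffles can give), but windows of 40 genes peaked on chromosome 10 (p = 0.003). A larger share of tubule RNA as the whole cause is argued against by the same window of 20 genes being highest with the proximal marker mean in the model (permutation p = 0.019), where Cyp2c23, Cpn1 and Abcc2 had log2 changes of 4.55, 3.06 and 1.53, although the mean t was then 1.14, none of these genes passed adjustment and windows of 40 genes gave p = 0.071. The other genes of the window that rose, Erlin1, Cox15, Pi4k2a, Pyroxd2 and Got1, were at 0.66, 0.43, 0.21, 0.04 and -0.12 with that covariate. Cnnm1 and Gm10768, which had not passed, went from 1.42 and 1.20 to -0.34 and -0.28. A tubule share can thus account for part of the cluster. A chromosome segment that differs between the KO and WT mice, for example one linked to the Cre transgene on the mixed background, may account for the rest. Counts per gene hold no variants, so this cannot be told apart from an effect of the loss of Parva, a gene on chromosome 7 that is floxed in both genotypes. That effect was not tested. Aldh1a1 and Dock8, which rose, and Cyp26a1, which fell, also lie on chromosome 19, from 20492583, 24999321 and 37697738, outside the window. Whether such a segment reaches them was not tested.

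Prm1, a protamine of sperm, had 140, 69 and 39 reads in KO-1, KO-2 and KO-3 and 0 in each WT library, at least 83.8-fold higher in KO against a floor of 3 counts over the WT group. Testis or sperm RNA is argued against by 0 reads of Prm2, Tnp1 and Tnp2 together in the KO libraries, beside 248 reads of Prm1. A Cre transgene that carries the 3' end of Prm1 may be the source, though the labels do not describe the construct. Induction of the endogenous Prm1 gene in KO glomeruli, with reads in all 3 KO libraries, cannot be told apart from this, since a count per gene does not show which part of the transcript the reads cover.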
